A study of Homo sapiens with 8 samples.

How the data were processed

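The series holds array scans of WI-38 fibroblasts that were proliferating, in replicative senescence or made senescent by irradiation, with the m6A immunoprecipitate (IP) in Cy5 and the supernatant in Cy3 on the same array, per the labels' protocols. No dye swap was made, so dye and fraction go together on every array. The arrays were scanned on an Agilent G2505C scanner and read with Agilent Feature Extraction 11.0.1.1, per the labels' protocols. The deposited values are signal intensities per spot and channel, with the local background and flags beside them. Per the file headers, the processed signal intensities are background-subtracted, detrended across the slide and dye-normalised within the array by a linear factor and a lowess curve. Checked against the background-subtracted signals, this step changed the log2 ratio of IP to supernatant by an amount that differed between spots, on proliferating replicate 1 from 0.226 at the 5th percentile to 1.73 at the 95th. The labels state that raw intensities were then scaled by the authors with spike-in RNA, and the deposited scanner values are from before that step. The files do not name which probes are the spike-in RNA.

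All values were computed from the processed signals on the log2 scale. Control spots and spots marked as uneven were left out, spots of 1 probe were averaged, and 843 of 60541 target probes with no even spot on some array were left out. The m6A level is the log2 of IP minus the log2 of supernatant, centred on the median of the tested probes of each array, since the spike-in probes planned for scaling were not named. Before centring the median lay between -0.28 and 0.12, and the dye normalisation sets it near 0, so a shift of most RNAs between IP and supernatant was not measured. The planned tests of the median m6A level were therefore not made. Total abundance is the log2 of the sum of both channels, with IP first rescaled by the array's median ratio, minus the 75th percentile of the 7877 probes above background in both channels on all arrays. A probe was tested for m6A level when both channels were above background on every array of at least 1 group (11578 probes), and for total abundance when at least 1 channel was (19598 probes). No spot of a target probe was saturated.

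The 3 groups were fitted together over the 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p values were adjusted over all tested probes by the method of Benjamini and Hochberg, with 0.05 as the threshold. Comparisons were each senescence type against proliferating, both types against proliferating, and irradiation against replicative senescence. The scan run was read from the file headers. Slide as a block was planned, and the fit within the 6 arrays of run 1 was added after the data were examined. In run 1 irradiation has 1 array, which is assumed to vary like the other groups. Gene lists were tested with limma's camera at a preset correlation of 0.01, repeated with an estimated correlation, and with fry, adjusted over the lists of a comparison and measure. Of 24 lists with 597 genes, 8 genes had a named probe, and cell cycle and mitosis, DNA replication and repair, and extracellular matrix had at least 2 tested genes. The unchanged groups behind the simulated correlations were drawn 100 times.

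Gene symbols came from a reference table that pairs transcripts with symbols, for 50 probes of 10 spots each. The array design is on build hg19 per the file headers, and no positions were used. Named genes were to be the 6 largest rises and falls among genes past the threshold, above background in both channels on every array of both groups and with no overlap between groups, or the 5 smallest p in each direction where none qualified, beside members of the fixed lists. Of 246 probes past the threshold for total abundance after irradiation, 34 met these conditions and 0 of them were named, so the 5 smallest p were used. ATAD2, ITGB3BP, RAD54B, SPDL1 and WDHD1, the values of DTL and DSCC1 in replicative senescence and of PIMREG after irradiation, the named m6A levels over run 1, and the unnamed probes were chosen after their values were seen, and the adjustment over named probes alone was also added then. Where a gene was above background on 0 arrays of the senescent group, its fall is given as a floored fall. Each signal dimmer than the dimmest target probe above background on its array was raised to that probe. The floored fall is not a lower limit, since brighter undetected signals were kept and other treatments of background gave smaller falls.

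The fits were tested on simulated data with 50 probes changed at each of 4 sizes. Over all arrays, 22% of 4-fold and 72% of 8-fold changes of total abundance were recovered in replicative senescence and 30% and 88% in irradiation senescence, and within run 1 90% and 100% in replicative and 54% and 94% in irradiation senescence. For m6A level the shares over all arrays were 30% and 64% in replicative and 48% and 86% in irradiation senescence. No 2-fold change was recovered over all arrays, and a change of that size could not be detected. There were 6 to 14 false calls per comparison over all arrays and 9 to 21 within run 1, where total abundance had 14 in replicative and 21 in irradiation senescence.

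Alternatives fixed before the data were examined were other scaling, background correction, filters, sets of arrays, array weights, a trend in the spread, the replicate number and the slide as blocks, leaving out each array, a fold minimum of 1.5 and other measures of level and abundance. The files give median but no mean foreground signals, so alternatives planned on mean signals used medians, and normexp used an offset of 50. The loess alternative started from the normexp signals. For total abundance it used the mean of the channels' log2 signals with quantile scaling, and for m6A level no quantile step was made. Scaling by the 12 ASSPINKEIN probes above background on all arrays, by the ERCC-00062 control probe and by the 75th percentile over all probes was added after the data were examined.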

Results

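The array series measured N6-methyladenosine (m6A), a methyl mark on adenosines of RNA, in WI-38 cells, an established line of human diploid lung fibroblasts. Total RNA of each culture was immunoprecipitated with an antibody against m6A, and the bound RNA (IP, labelled with Cy5) and the RNA left in the supernatant (labelled with Cy3) were hybridised together to 1 array of 62976 spots. The 8 arrays analysed here came from 3 proliferating cultures at population doubling level 22, 2 cultures in replicative senescence at population doubling level 50, and 3 cultures made senescent by 10 Gy of ionising radiation and collected 10 days later at population doubling level 22. Senescence is a lasting arrest of division. The design text states 3 biological replicates per condition, and replicate 1 of replicative senescence was not analysed here. The number of arrays limits the precision of every value. The arrays were scanned in 2 runs: run 1 held the 3 proliferating arrays, both replicative senescence arrays and irradiation replicate 1, and run 2 held irradiation replicates 2 and 3.

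Between 10570 and 12106 target probes per array were above background in both channels in run 1, against 20694 to 24487 in run 2. The correlation of m6A levels across probes was 0.856 to 0.957 between arrays of run 1, 0.864 between the 2 arrays of run 2, and 0.371 to 0.613 between arrays of different runs. For total abundance the ranges were 0.927 to 0.984 within run 1 and 0.822 to 0.926 between runs, with 0.934 within run 2. Probes are not independent replicates. The first principal component of the m6A levels took 63.6% of their variance and parted the arrays of run 2 from the rest. The 3 comparisons that involve irradiation are therefore given with scan run as a block and within run 1, where irradiation has 1 array.

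**Figure D1:**
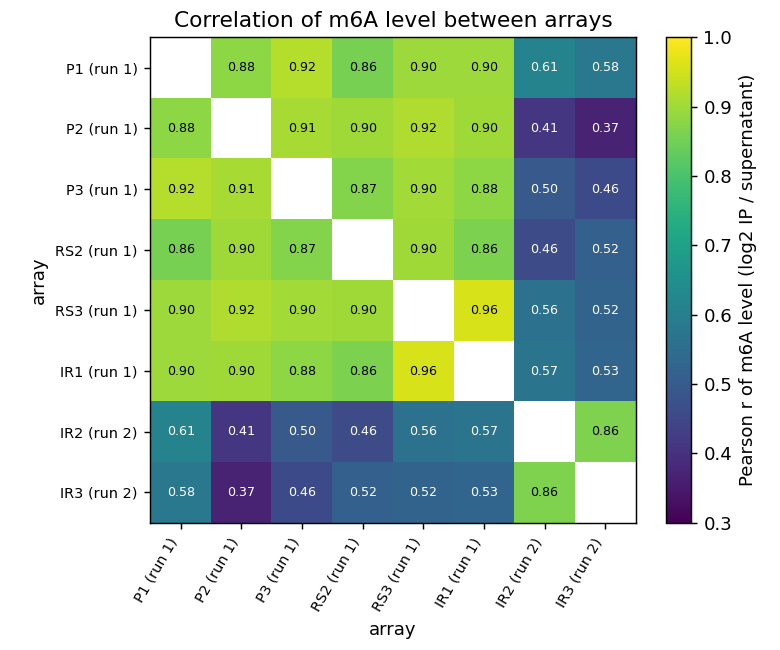
Pearson correlation across 11578 probes of the m6A level (log2 of IP over supernatant, centred on the array median) between each pair of the 8 arrays, P proliferating, RS replicative senescence and IR irradiation senescence, with the scan run in parentheses. Pairs from different runs lay between 0.371 and 0.613 and pairs within run 1 between 0.856 and 0.957.

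The files name 50 probes by a transcript that the reference table pairs with a protein-coding gene symbol, and all values given for genes refer to those probes. The other 60491 target probes carry only the array maker's identifiers and no position was read for them, so PTCHD4, the gene in the series title, could not be located and has no value here. Of the fixed gene lists, 3 had at least 2 named and tested genes. The m6A writers and the m6A erasers had 0 named probes among 10 and 2 genes.

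The first comparison asks which RNAs differed in total abundance (IP and supernatant signal together) between replicative senescence and proliferating cells. All of these arrays lie in run 1, and within the 6 arrays of that run 13 of the 37 named genes tested fell and 0 rose. That fit was added after the data were examined, and in the planned fit of all 8 arrays 0 of the 37 passed. The cell cycle and mitosis genes fell: CCNA2, which encodes cyclin A, fell by 3.79 on the log2 scale (SE 0.33, limma adjusted p = 0.00206), KIF20A, a mitotic kinesin, fell by 3.94 (SE 0.39, adjusted p = 0.00218), and CENPE, a kinetochore motor, fell by 2.63 (SE 0.36, adjusted p = 0.0067), with 3 proliferating against 2 senescent arrays. CCNA2 and CENPE were above background on 0 of the 2 senescent arrays, and on the background-subtracted signals their floored falls were 8.49-fold and 3.93-fold. KIF20A, PIMREG, CHAF1B and EXO1 were above background on 1 of the 2, so part of each of their senescent means is signal at background. PIMREG fell by 4.14 (SE 0.46, adjusted p = 0.00328), and CHAF1B, a subunit of a histone chaperone active at replication forks, fell by 3.30 (SE 0.44, adjusted p = 0.00583). Among the genes of DNA replication and repair, EXO1, an exonuclease, fell by 3.31 (SE 0.38, adjusted p = 0.00346), and BRCA1 was 1.71 lower on the log2 scale (SE 0.43) without passing (adjusted p = 0.0602). SPDL1, ATAD2 and WDHD1, each above background on 1 senescent array, also fell, with log2 changes of -2.65, -2.38 and -2.21. DTL, DSCC1, ITGB3BP and RAD54B were above background on 0 of the 2 senescent arrays. Their floored falls were 5.12-fold, 3.41-fold, 2.63-fold and 2.79-fold on the same signals. In proliferating cells the supernatant of EXO1, BRCA1, ATAD2, CENPE, RAD54B and WDHD1 was above background on 0 of the 3 arrays. That of KIF20A, DTL and DSCC1 was so on 1. The total abundance of these genes rests mainly on the IP channel, and their m6A level was not tested. Less RNA and a lower share bound by the antibody cannot be told apart for them. The sizes and the floored falls depend on the treatment of background. In fits of all 8 arrays CCNA2 was at -1.01 with normexp correction (adjusted p = 0.999) and -1.06 with loess and quantile scaling (adjusted p = 0.0152). CENPE was at -0.60 and -0.50 (adjusted p = 0.999 and 0.119).

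Of 19598 probes tested within run 1, 864 passed, 160 higher and 704 lower in replicative senescence. With the 75th percentile taken over all probes the counts were 300 higher and 305 lower, with 13 named genes lower, and with loess and quantile scaling 94 higher and 166 lower, with 5 named genes lower. With all 8 arrays in one fit, 0 probes passed in limma (1181 had an unadjusted p under 0.05), and with scan run as a block 0 passed (1399 unadjusted). In the fit of all 8 arrays the 13 genes had the same log2 changes with larger errors, and CCNA2 and PIMREG had an adjusted p of 0.0611 and KIF20A 0.0663. The 13 genes passed there when the adjustment was made over the 37 named probes alone. Without irradiation replicate 2 or 3, 125 and 110 probes passed in the fit of the remaining arrays. The matrix genes LOX and LOXL2, which encode enzymes that cross-link collagen, were at -0.05 (SE 0.69) and 0.04 (SE 0.53), with adjusted p = 1 for each. RND3, a small GTPase, and COL13A1, a collagen, were 1.06 higher (SE 0.54, adjusted p = 0.914) and 0.28 higher (SE 0.52, adjusted p = 1). The errors and p values of LOX, LOXL2, RND3 and COL13A1 are from the fit of all 8 arrays. Within run 1 the changes were the same with smaller errors, and none of them passed. RND3 had an SE of 0.38 there (limma adjusted p = 0.152) and COL13A1 of 0.33 (adjusted p = 0.719). RND3 was higher on both senescent arrays than on any proliferating array. LOXL2, COL13A1 and RND3 were the 3 named genes with a higher mean.

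Irradiation senescence was compared with proliferating cells in the same way. With all 8 arrays, 9 of the 37 named genes fell and 0 rose. CCNA2 fell by 4.20 on the log2 scale (SE 0.58, limma adjusted p = 0.0092), with a level of -3.85 ± 0.32 (SD, n = 3) in proliferating and -8.04 ± 1.16 (SD, n = 3) in irradiated cells. CCNA2, KIF20A, CENPE and ITGB3BP were above background on 2 of the 3 irradiated arrays, so part of their irradiated means is signal at background. CCNA2 and ITGB3BP were so in the supernatant channel alone. EXO1, above background on 1 of the 3 irradiated arrays, fell by 4.19 (SE 0.70, adjusted p = 0.0164), KIF20A fell by 3.44 (SE 0.65, adjusted p = 0.0224) and CENPE fell by 2.92 (SE 0.55, adjusted p = 0.0223). DTL, part of a ubiquitin ligase that acts in S phase, and DSCC1, a cohesion factor, were above background on 0 of the 3 irradiated arrays. Their floored falls were 13.2-fold and 8.27-fold on the background-subtracted signals (limma adjusted p of the fitted changes = 0.0151 and 0.0223). Within run 1 their log2 changes were -3.40 and -3.26. The supernatant of EXO1 and CENPE was above background on 0 of the 3 proliferating arrays, and that of KIF20A, DTL and DSCC1 on 1. The falls of these genes rest mainly on the IP channel, so less RNA and a lower bound share cannot be told apart. CHAF1B, PIMREG and ITGB3BP fell as well, with log2 changes of -3.55, -2.91 and -2.68 (adjusted p = 0.0223, 0.0319 and 0.0237). Other treatments of background gave smaller falls: CCNA2 fell by 1.80 with normexp correction and fell by 1.07 with loess and quantile scaling (adjusted p = 0.00933 and 0.00607), EXO1 fell by 0.81 and DTL fell by 0.74 with loess (adjusted p = 0.016 and 0.0154), and DSCC1 was at -1.40 with normexp (adjusted p = 0.0836) and -0.54 with loess (adjusted p = 0.0411). CENPE and ITGB3BP passed with neither, at -1.36 and -1.28 with normexp (adjusted p = 0.0962 and 0.13) and -0.48 and -0.42 with loess (adjusted p = 0.061 and 0.0842). The loess values start from the normexp signals, so these treatments are not independent. BRCA1 was 2.02 lower (SE 0.60, adjusted p = 0.131). Irradiation replicate 3 was the lowest irradiated array for CCNA2, EXO1, CENPE, DTL, DSCC1, CHAF1B and ITGB3BP, but not for KIF20A and PIMREG. EXO1 was at -10.3 there, against -7.95 and -7.07 on replicates 1 and 2. Replicate 3 was also low in total GAPDH 3' signal (0.744 against 2.32 to 3.27 on the others), so these sizes lean partly on that array.

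Each of these 9 genes was lower on all 3 irradiated arrays than on any proliferating array. Within run 1, where irradiation has 1 array, 12 of the 37 genes passed and all 12 were lower, with CCNA2 at -4.51 (adjusted p = 0.00276), KIF20A at -4.29 (adjusted p = 0.00536) and EXO1 at -3.71 (adjusted p = 0.00826). With scan run as a block, CCNA2 was again at -4.51, and 0 of the 37 genes passed in limma (CCNA2 adjusted p = 0.18). The block leaves irradiation replicate 1 alone to set the change, and the error includes the spread between irradiation replicates 2 and 3. POLR2A, the large subunit of RNA polymerase II, was 1.36 higher (SE 0.55, adjusted p = 0.243) and 0.27 higher within run 1. RND3 was 0.86 higher (SE 0.48, adjusted p = 0.381), LOX 0.08 higher (SE 0.61, adjusted p = 0.956) and LOXL2 0.24 lower (SE 0.47, adjusted p = 0.815). These 4 genes did not pass.

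**Figure D2:**
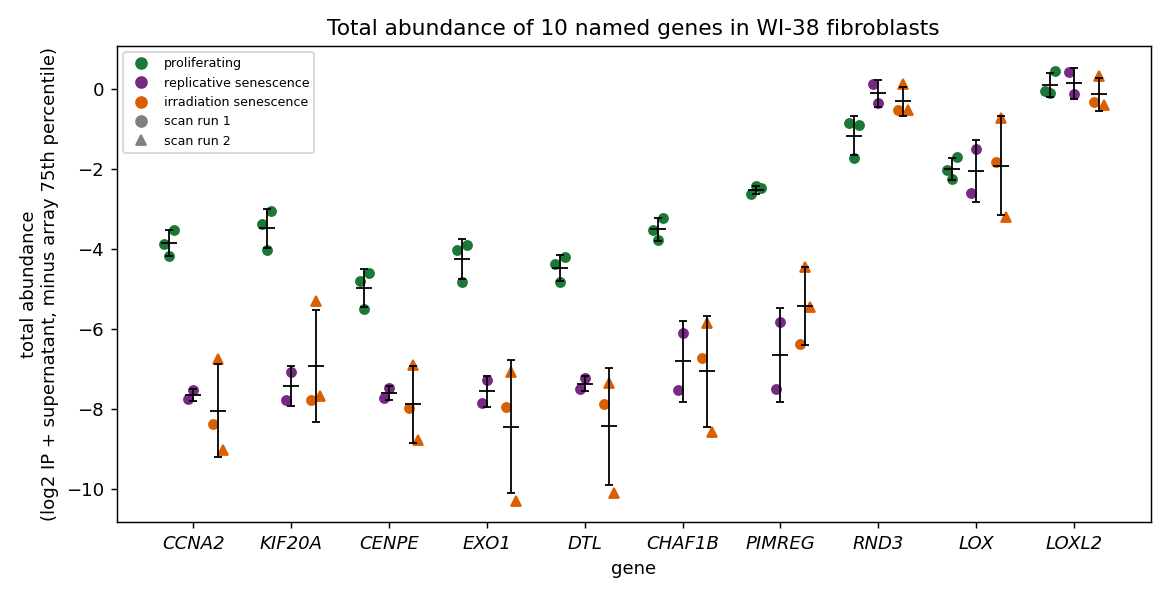
Total abundance (log2 of IP plus supernatant signal, minus the 75th percentile of the array) of 10 named genes. Each point is 1 array, circles from scan run 1 and triangles from run 2, and black bars give the mean and SD of the 3 proliferating, 2 replicative senescence and 3 irradiation arrays. CCNA2 lay at -3.85 in proliferating, -7.64 in replicative senescence and -8.04 in irradiation senescence, while LOXL2 lay at 0.11, 0.15 and -0.13.

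Over all 19598 probes, 246 passed in irradiation senescence against proliferating, 33 higher and 213 lower, with 3292 at an unadjusted p under 0.05. Of the 246, 212 were not above background in both channels on every array of these groups, and the 9 named genes are among the 212. Within run 1, 59 probes were higher and 423 lower, and with scan run as a block 1 was higher and 0 lower (1486 unadjusted). Without irradiation replicate 1 the count rose to 2312 and the direction turned, with 1654 higher and 658 lower. Leaving out proliferating replicate 1, 2 or 3 gave 8, 41 and 7 probes, leaving out either replicative senescence array gave 149, and leaving out irradiation replicate 2 or 3 gave 1664 and 53.

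With the mean of both senescent groups set against proliferating, 226 probes passed, 44 higher and 182 lower, and with scan run as a block 37 passed, 6 higher and 31 lower. Within run 1 the counts were 187 higher and 1450 lower. Leaving out proliferating replicate 1, 2 or 3 gave 16, 63 and 7 probes, leaving out replicative senescence replicate 2 or 3 gave 15 and 123, and leaving out irradiation replicate 1 or 2 gave 447 (213 higher and 234 lower) and 1111 (112 higher and 999 lower). The unnamed probe ASHG19AP1B10021478111 was higher by 2.31 on the log2 scale (adjusted p = 0.0165) and the unnamed probe ASHG19AP1B10014033711 lower by a log2 change of -3.50 (adjusted p = 0.00443). Both were picked for their size among probes whose 5 senescent arrays did not overlap the 3 proliferating ones, so the lack of overlap adds no evidence. In replicative senescence they passed within run 1 (limma adjusted p = 0.00417 and 0.00291). With scan run as a block they did not (adjusted p = 0.105 and 0.0975). After irradiation their log2 changes with the block were 2.17 and -4.26, set by irradiation replicate 1 alone. The difference between irradiation and replicative senescence was tested directly, and 0 probes passed in limma (1205 unadjusted), 0 with scan run as a block (478 unadjusted) and 5 within run 1, all 5 higher after irradiation. Without irradiation replicate 1, 1403 passed, 1176 of them higher after irradiation.

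The gene lists were tested against all other probes with camera. For cell cycle and mitosis (CCNA2, CENPE and KIF20A) the median log2 change was -3.79 in replicative senescence (adjusted p = 3.11e-09) and -3.44 in irradiation senescence (adjusted p = 6.41e-06), and all 3 genes were lower in each. With CCNA2 and CENPE set to their floored falls the median in replicative senescence was -3.09. With an estimated correlation the adjusted p was 0.0446 in replicative and 0.0974 in irradiation senescence. For DNA replication and repair (BRCA1 and EXO1) the medians were -2.51 (adjusted p = 0.000528) and -3.10 (adjusted p = 0.00163), and with an estimated correlation the adjusted p was 0.0742 and 0.0974. The self-contained test fry gave an adjusted p of 0.0144 and 0.00787 for cell cycle and mitosis and 0.0562 and 0.0175 for DNA replication and repair, so the latter did not pass in replicative senescence. With scan run as a block, the preset correlation gave an adjusted p of 2.73e-07 and 5.31e-06 for cell cycle and mitosis and 0.00288 and 0.0341 for DNA replication and repair, and the estimated correlation gave an adjusted p of 0.105 and 0.145 for the first list and 0.133 and 0.263 for the other. Within run 1 the preset correlation gave an adjusted p of 3.1e-06 and 1.71e-05 for the first list and 0.00268 and 0.0184 for the other, and the estimated correlation an adjusted p of 0.161 and 0.221, and 0.161 and 0.249. With an estimated correlation neither list therefore passed with the block or within run 1. With fry the adjusted p with the block was 0.0326 and 0.0459 for cell cycle and mitosis and 0.0895 and 0.152 for DNA replication and repair, which did not pass, and within run 1 both lists passed (adjusted p = 0.00611 and 0.00814, and 0.0187 and 0.0309). For the extracellular matrix list (LOX and LOXL2) the medians were -0.005 (adjusted p = 0.648) and -0.08 (adjusted p = 0.993).

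The question of the m6A comparison is whether the share of an RNA bound by the antibody differed in senescent cells. In proliferating and replicative senescence cells and irradiation replicate 1, the arrays of run 1, LOXL2 had an m6A level of 3.44 ± 0.81 (SD, n = 6) on the log2 scale above the array median, COL13A1 3.12 ± 0.62, DNTTIP2 2.58 ± 0.59, the translation factor gene EIF5B 2.31 ± 0.83 and LOX 1.95 ± 0.68. Of the 17 named genes tested, 13 lay above the median of their array on all 8 arrays. Some of these values rest on signals at background. CHAF1B and NMI were above background in both channels on 0 of the 2 replicative senescence arrays, and BAZ1A and ERGIC2 on 1. CHAF1B was so on 1 of the 3 irradiated arrays. The levels are relative to the median of each array, so a change shared by most RNAs could not be seen.

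In replicative senescence, 0 of the 17 named genes passed in limma (0 at an unadjusted p under 0.05). The smallest p among lower levels belonged to LOXL2, at 3.96 ± 0.86 (SD, n = 3) in proliferating and 2.81 ± 0.24 (SD, n = 2) in senescent cells (log2 change -1.15, adjusted p = 0.898), then RND3 at -0.80, LOX at -0.60, PIMREG at -0.81 and EIF5B at -0.55. Among higher levels they were ABRAXAS1 at 0.72 (adjusted p = 0.935), POGLUT2 at 0.42, ERGIC2 at 0.31, NMI at 0.10 and POLR2A at 0.08. ABRAXAS1 and NMI were above background in both channels on 0 of the 2 senescent arrays, so their senescent values rest on signals at background. Across all 11578 probes 1 passed and was lower, with 563 at an unadjusted p under 0.05. Within run 1 and with scan run as a block 1 probe was lower and 1 higher, and without replicative senescence replicate 2 the count was 0.

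In irradiation senescence 0 of the 17 named genes passed in limma and 3 had an unadjusted p under 0.05. Those 3 were RHOH, a GTPase gene known from blood cells, at -3.81 (SE 1.14, adjusted p = 0.103), PIMREG at -2.27 (SE 0.75, adjusted p = 0.131) and ABRAXAS1 at 1.22 (SE 0.51, adjusted p = 0.224). The RHOH probe had a mean level of 5.23 in run 1 and 0.096 in run 2, and what it detects was not tested. PIMREG was above background in both channels on 1 of the 3 irradiated arrays and CCNA2 on 0. Within run 1 the changes of RHOH, PIMREG and ABRAXAS1 were -0.51, -0.49 and 0.49 (adjusted p = 0.862, 0.841 and 0.873). LOXL2, POLR2A and CCNA2 followed among lower levels at -0.98, -0.61 and -0.44, and POGLUT2, NMI, ERGIC2 and NOC3L among higher levels at 0.92, 0.56, 0.58 and 0.51. Within run 1, POLR2A was at 0.66, CCNA2 at 0.13, ERGIC2 at -0.52 and NOC3L at -0.02, so the direction of these 4 turned. Across all probes 1 passed and was lower, with 2343 at an unadjusted p under 0.05, and 1 passed within run 1 and with scan run as a block. Without irradiation replicate 1 the count was 2005, 532 higher and 1473 lower.

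A single probe passed for m6A level in both senescence types. The unnamed probe ASHG19AP1B10014277411 had a level of 0.86 ± 0.42 (SD, n = 3) in proliferating cells, -4.65 ± 0.25 (SD, n = 2) in replicative senescence and -3.94 ± 0.15 (SD, n = 3) in irradiation senescence. Its level fell by 5.51 (SE 0.41, limma adjusted p = 0.00133) in replicative and fell by 4.80 (SE 0.36, adjusted p = 0.0017) in irradiation senescence, with log2 changes of -5.51 and -4.95 with scan run as a block (adjusted p = 4.66e-05 and 0.00308). The mean log2 IP signal changed by -7.60 and -7.78, the supernatant signal by -2.16 and -3.16, and total abundance by -3.71 and -4.67 (adjusted p = 0.0611 and 0.00499). With scan run as a block its total abundance passed in neither type (limma adjusted p = 0.11 and 0.18). In replicative senescence the fall in total abundance passed within run 1 (adjusted p = 0.00206). With normexp background correction its level changes were -2.19 and -2.16 and did not pass (adjusted p = 0.223 and 0.0669). The RNA that this probe detects is not identified here.

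With both senescent groups together, m6A levels gave 1 probe, the same one, lower by a log2 change of -5.16 (adjusted p = 0.000329), and 1682 at an unadjusted p under 0.05. Without irradiation replicate 1 the count was 1126. Irradiation against replicative senescence gave 0 probes in limma (1287 unadjusted), 0 within run 1 (247 unadjusted) and 0 with scan run as a block (285 unadjusted), against 1232 without irradiation replicate 1. The extracellular matrix genes LOX and LOXL2 had a median m6A change of -0.87 in replicative senescence (camera adjusted p = 0.0762) and -0.65 in irradiation senescence (adjusted p = 0.362).

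Both senescence types were set against the same 3 proliferating arrays, so their changes share chance values. Within run 1, 317 probes were lower in both types and 30 higher in both, against 15.2 and 0.482 for independent lists. Across probes within run 1 the log2 changes of total abundance in the 2 types had a Pearson correlation of 0.652 (0.317 in simulated unchanged groups) and a covariance of 0.374 (0.0745 simulated). With all 8 arrays the correlation was 0.625 (0.448 simulated) and the covariance 0.433 (0.191 simulated), and with scan run as a block 0.652 (0.318 simulated) and 0.374 (0.147 simulated). The block gives the same fitted changes as run 1 alone, so its values are not a separate result. For m6A level the covariance was 0.357 over all arrays (0.178 simulated) and 0.245 within run 1 (0.114 simulated), with correlations of 0.499 (0.447 simulated) and 0.564 (0.316 simulated). The 3 proliferating arrays could not be parted into groups of 2, so part of the excess may come from the shared arrays. Irradiation replicate 1 and replicative senescence replicate 3 were the most alike pair of arrays, with a correlation of 0.984 for total abundance. Dye normalisation moved their median log2 ratio by -0.972 and -1.07. The shift was -0.0512 to 0.555 on proliferating arrays and -0.152 on replicative senescence replicate 2. The simulated values were drawn independently for each probe, so a technical likeness of these arrays is not covered by them.

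The last comparison asks whether m6A level and total abundance moved together across the 11578 probes. The Pearson correlation of the log2 changes was 0.009 in replicative senescence (Spearman 0.0201) and 0.195 in irradiation senescence (Spearman 0.174), and within run 1 the latter was 0.344 (Spearman 0.389). For both senescent groups together it was 0.170 (Spearman 0.208). Both measures are built from the same 2 channels, so they share errors.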

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

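The tests of scan run, irradiation and scaling below, and those of RNA integrity and splits within run 1, were chosen after the result was seen, and the test on bright probes and the counts of other splits were set before. Signals were found in probes that the comparisons leave out. Of 102 ASSPINKEIN probes, 12 were above background in both channels on all 8 arrays, and so were 16 of 20 CUST probes, against 0 of 60 Negative probes. The control probe ERCC-00062 was above background in both channels on 8 arrays. The files do not say what the ASSPINKEIN and CUST probes detect. ASSPINKEIN100006756 had a level between 5.85 and 7.66 above the array median in run 1 and between 0.347 and 1.06 in run 2.

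Irradiation replicates 2 and 3 stood apart from the other arrays in m6A level. Irradiation replicate 1 had a mean correlation of 0.893 with the proliferating arrays of its own run and 0.549 with the other irradiation replicates, a difference of 0.344. This follows from the pattern itself, so it does not decide for a difference between scan runs, which stays open. Its correlation with irradiation replicates 2 and 3 exceeded that of the proliferating arrays by 0.061, less than the SD of 0.103 over the proliferating arrays. This rests on 1 array, so irradiation stays open as well. Among the 2895 probes with the brightest signals the mean correlation between runs was 0.555, below the lowest value within run 1 of 0.926, which argues against the noise of dim probes. A difference in culture or labelling that goes with the run stays open and was not tested.

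Most calls of total abundance in senescent cells were lower. Over 5 scalings the lowest share of lower calls for both senescent groups against proliferating was 67.0%, with the percentile taken over all probes. This argues against scaling as the whole source for that comparison when all arrays are included. Without irradiation replicate 1 the share was 52.4% (213 higher and 234 lower) with the scaling used for the reported counts. The other scalings were not tested without that array, so scaling stays open there. For replicative senescence scaling stays open: within run 1 the lowest share was 50.4% (300 higher and 305 lower), and over all arrays 3 of 3 calls were higher with ERCC-00062 scaling and 29 of 64 with the percentile over all probes. The log2 ratio of 3' to 5' GAPDH control probes was 0.16 higher in irradiated than in proliferating cells, less than the SD of 0.186 over the proliferating arrays. On irradiation replicate 3 the total GAPDH 3' signal was 0.744 on the log2 scale, against 2.32 to 3.27 on the other 7 arrays, and LOX and MTDH were at -3.19 and -5.60 against -0.715 and -3.50 on replicate 2, so a difference in RNA quality stays open. Without that array 44 of 53 calls after irradiation were lower. For both senescent groups against proliferating 226 probes passed, and 2 of 100 splits drawn gave as many, the real one included. The highest other count was 282, from a split that kept the 3 proliferating arrays together and mixed the senescent ones. These splits exchange arrays between the scan runs. With scan run as a block and only the labels of the 6 arrays of run 1 exchanged, 37 probes passed and 2 of 60 splits gave as many, the real one included. The other of the 2 gave 95 and also kept the 3 proliferating arrays together. All splits with other proliferating arrays gave 0. Each choice of proliferating arrays occurs in 3 of the 60 splits. Counted by that choice the share could not fall under 0.05, so chance is not excluded. A fall of dividing-cell RNAs in senescence stays among the open explanations. Over all probes the direction turned without irradiation replicate 1 for irradiation against proliferating (2312 probes, 28.5% lower).

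For irradiation senescence against proliferating, total abundance gave 246 probes and the highest other of the 10 splits gave 0. In 1 of the 10 splits, the real one, as many passed, and 10 splits are too few for a share under 0.05. For m6A level the real split gave 1 probe and the highest other also 1, in 2 of 10 splits, again too few. For both senescent groups against proliferating in m6A level, 1 probe passed, and 7 of 100 splits gave as many, so chance is not excluded for the count. With scan run as a block 1 passed as well, and 8 of 60 splits within run 1 gave as many. Among the 100 splits the highest other gave 862 probes and set the 2 arrays of run 2 as a group of their own. The cause of that count was not tested. Within run 1 the count was 1.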

How the results depend on the processing

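The fits within run 1, the scalings on ASSPINKEIN, ERCC-00062 and all probes, and all alternatives of the 2 kinds of correlation were chosen after seeing the data. PTCHD4 has no named probe and the median m6A level has no scale, so the alternatives set for them were not run, and the planned centring on the median is the scaling used. Counts below are probes past limma's adjusted threshold, in the order replicative senescence against proliferating, irradiation senescence against proliferating, both against proliferating, and irradiation against replicative senescence, and the cause of each change was not tested unless stated. A spot near background limits what can be seen: 212 of the 246 probes for total abundance after irradiation were not above background in both channels on every array of the 2 groups compared, which leaves 34. A filter that asks for both channels on all 8 arrays, with p adjusted over the probes it keeps, gave 0, 4, 6 and 0 probes.

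For m6A level (1, 1, 1 and 0 probes as reported) loess and normexp each gave 0, 0, 0 and 0, and the probe ASHG19AP1B10014277411 had a level change of -2.23 and -1.92 with loess (adjusted p = 0.525 and 0.0727) and of -2.19 and -2.16 with normexp (adjusted p = 0.223 and 0.0669). It passed in 18 of 21 alternatives for replicative and 19 of 21 for irradiation senescence and was lower in all of them. Loess starts from the normexp signals, so those alternatives are not independent. Raw signals gave 1, 1, 2 and 0. Array weights gave 2, 3314, 1375 and 1913, from an estimate of the weights that did not converge fully. A trend in the spread gave 2, 6, 1 and 0, percent modified gave 1, 2, 2 and 0, and fits of only the groups compared gave 2, 1 and 0. Run 1 alone and scan run as a block each gave 2, 1, 1 and 0. Leaving out 1 array gave 0 to 2, 1 to 2005, 1 to 1126 and 0 to 1232, the highest without irradiation replicate 1, which leaves irradiation to run 2 alone.

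For total abundance (0, 246, 226 and 0 probes as reported) loess gave 114, 276, 325 and 0, raw signals 56, 1105, 302 and 8, and normexp 25, 400, 166 and 33. No filter gave 83, 11514, 361 and 3, with 10972 of the 11514 lower. Fits of only the groups compared gave 864, 149 and 0, array weights 866, 361, 1719 and 0, and a trend in the spread 79, 768, 320 and 0. Scan run as a block gave 0, 1, 37 and 0, and run 1 alone 864, 482, 1637 and 5. ASSPINKEIN scaling gave 40, 354, 278 and 0, ERCC-00062 scaling 3 (all higher), 4, 38 and 0, and the 75th percentile over all probes 64 (29 higher and 35 lower), 392, 351 and 2. The mean of the log2 signals gave 9, 258, 245 and 0 and the supernatant alone 0, 161, 85 and 0. Leaving out 1 array gave 0 to 125, 7 to 2312, 7 to 1111 and 0 to 1403. A fold minimum of 1.5 changed no count of either measure.

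No pairing by replicate number was seen. The correlation of deviations from the group mean was -0.303 to 0.125 between arrays of the same number for m6A level and -0.409 to 0.241 for total abundance. This check cannot exclude pairing, since deviations within a group sum to 0 and those of irradiation hold the difference between scan runs. The replicate block gave 1, 476, 1 and 0 probes for m6A level and 0, 305, 192 and 0 for total abundance.

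The fitted changes with scan run as a block and in run 1 alone are the same by construction. The correlation of m6A change with abundance change after irradiation was therefore 0.344 in both. Leaving out 1 array moved it between 0.103 and 0.253, and between -0.117 and 0.196 in replicative senescence, where its sign is not settled. For the 2 senescence types the correlation of changes ran from 0.354 to 0.571 for m6A level and from 0.526 to 0.681 for total abundance.

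Among the named genes, CCNA2, EXO1 and DTL were lower in total abundance after irradiation in all 23 alternatives and passed in 19, with log2 changes from -4.84 to -1.07, from -4.87 to -0.81 and from -4.51 to -0.74, the smallest with loess and quantile scaling. The call of CCNA2 ended with scan run as a block (adjusted p = 0.18, the highest of its alternatives, down to 0.000101). CENPE passed in 14 of 23, the fewest of the 9 genes, and in replicative senescence PIMREG passed in 12 of 23 and CCNA2 in 10. The DNA replication and repair list lost its call in replicative senescence with normexp (median -0.65, adjusted p = 0.0545), and with an estimated correlation the adjusted p for both senescent groups was 0.0624 for cell cycle and mitosis and 0.0702 for DNA replication and repair. In all, 1242 alternatives of named genes and probes kept direction and side, 80 kept direction and lost the call, 160 kept direction and gained one, and 62 turned direction, and for gene lists 94 kept both, 6 lost the call and 17 turned direction.

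The log2 values that turned direction all belong to genes and lists that passed in neither fit. Loess gave NMI -0.31, ERGIC2 -0.082 (m6A level, replicative senescence), LOX 0.052 (m6A level, irradiation senescence), LOX 0.24, the extracellular matrix median 0.35 (total abundance, replicative senescence). It also gave the extracellular matrix median 0.035 (total abundance, irradiation senescence), the extracellular matrix median 0.19 (total abundance, both senescent groups). Raw signals gave NMI -0.35, ERGIC2 -0.042 (m6A level, replicative senescence), LOX 0.005 (m6A level, irradiation senescence), LOX 0.051, the extracellular matrix median 0.18 (total abundance, replicative senescence). It also gave LOXL2 0.042, the extracellular matrix median 0.029 (total abundance, irradiation senescence), the extracellular matrix median 0.11 (total abundance, both senescent groups). Normexp gave RND3 0.14, NMI -0.36, ERGIC2 -0.096, ABRAXAS1 -0.086 (m6A level, replicative senescence), LOXL2 0.044, LOX 0.18, NMI -0.11, the extracellular matrix median 0.11 (m6A level, irradiation senescence), the extracellular matrix median 0.023 (m6A level, both senescent groups). It also gave LOX 0.12, the extracellular matrix median 0.25 (total abundance, replicative senescence), LOXL2 0.060, LOX -0.039, the extracellular matrix median 0.010 (total abundance, irradiation senescence), the extracellular matrix median 0.13 (total abundance, both senescent groups). No filter gave CCNA2 0.087 (m6A level, replicative senescence). Replicate block gave CCNA2 0.17 (m6A level, replicative senescence), LOXL2 -0.041 (total abundance, replicative senescence). Scan run as a block gave POLR2A 0.66, CCNA2 0.12, NOC3L -0.024, ERGIC2 -0.52 (m6A level, irradiation senescence). Scan run 1 arrays only gave POLR2A 0.66, CCNA2 0.12, NOC3L -0.024, ERGIC2 -0.52 (m6A level, irradiation senescence), the same fitted changes as with the block. ASSPINKEIN scaling gave CCNA2 0.41 (m6A level, replicative senescence), POLR2A 0.19, CCNA2 0.36, LOX 0.49, the extracellular matrix median 0.16 (m6A level, irradiation senescence), LOXL2 0.17, the extracellular matrix median 0.28 (total abundance, irradiation senescence). It also gave the extracellular matrix median 0 (total abundance, replicative senescence), the extracellular matrix median 0.14 (total abundance, both senescent groups). ERCC-00062 scaling gave POLR2A -0.48, NMI -0.46, ERGIC2 -0.25, POGLUT2 -0.13 (m6A level, replicative senescence), LOXL2 -0.30, COL13A1 -0.056 (total abundance, replicative senescence). Array weights gave LOX -0.18 (total abundance, irradiation senescence). Mean of the channels' log2 signals gave LOX 0.12 (total abundance, replicative senescence), LOXL2 0.054 (total abundance, irradiation senescence). Supernatant alone gave LOX 0.40 (total abundance, replicative senescence), LOXL2 0.20, LOX -0.14 (total abundance, irradiation senescence). 75th percentile over all probes gave LOX 0.22, the extracellular matrix median 0.27 (total abundance, replicative senescence), the extracellular matrix median 0.079 (total abundance, both senescent groups). Leaving out 1 array gave -0.43 to 0.34 for CCNA2 (m6A level, replicative senescence), -0.21 to 0.36 for POLR2A (m6A level, replicative senescence), -0.29 to 0.42 for NMI (m6A level, replicative senescence). The other ranges were -0.70 to 0.15 for LOX (m6A level, irradiation senescence), -0.61 to 0.50 for LOX (total abundance, replicative senescence), -0.23 to 0.32 for LOXL2 (total abundance, replicative senescence), -0.52 to 0.72 for LOX (total abundance, irradiation senescence).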

Other observations

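The probe named for RHOH had an m6A level of 5.23 ± 0.63 (SD, n = 6) above the array median in run 1, and 0.096 in the 2 arrays of run 2. The probe ASSPINKEIN100006756, whose target the files do not state, had means of 6.79 and 0.702, and whether the RHOH probe detects its own transcript was not tested. Its total abundance was 4.87 ± 0.28 (SD, n = 3) above the 75th percentile in proliferating cells. POLR2A lay at 0.259 ± 0.357 (SD, n = 6) in run 1 and at -1.13 in run 2, and PIMREG at 0.461 ± 0.507 and -2.35. COL13A1 and DNTTIP2 differed less between the runs, with 3.12 and 2.58 in run 1 and 3.44 and 2.72 in run 2.

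Against the 12 ASSPINKEIN probes, the median m6A level of the tested probes was -1.15 ± 0.33 (SD, n = 3) in proliferating cells, -0.73 ± 0.19 (SD, n = 2) in replicative senescence and -0.83 on irradiation replicate 1, all in run 1, and -0.13 and -0.07 on irradiation replicates 2 and 3, in run 2. The exact permutation p for replicative senescence was 0.3, and the smallest it can give is 0.1. No p is given for irradiation, whose values part by scan run. Against ERCC-00062 the run 1 values were 0.29 in proliferating cells, -0.26 in replicative senescence (exact permutation p = 0.2) and -0.16 on irradiation replicate 1, so the direction turned with the probes chosen for scaling.

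A hypothesis set before the test was that probes with a higher starting m6A level fall more in abundance in senescence. The level on 1 proliferating array was set against the change from the other proliferating arrays, for replicative senescence and for irradiation replicate 1, in 3 rotations. The Spearman values across probes ran from 0.0456 to 0.119 in replicative senescence and from -0.0938 to -0.0258 for irradiation replicate 1. None of the 6 was below the bound of -0.1 set for the hypothesis, which argues against it as set. For irradiation the sign went with the hypothesis in all 3 rotations, on 1 irradiated array. Probes are not independent replicates.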
